A study of Mus musculus with 7 samples.

How the data were processed

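RNA was sequenced from bone marrow of 7 mouse samples, 3 flox and 4 KO, with poly(A) selection, per the labels' protocols. The extraction protocol in the labels speaks of white adipose tissue while the source label says bone marrow; the source label was followed. Read counts per Ensembl gene were deposited as raw counts in 1 table with a column per library. Reads were trimmed with Trimmomatic 0.36, aligned with STAR 2.5.2b to GRCm38 and counted with featureCounts of Subread 1.5.2, per the submitters' processing notes. The annotation release, the strand setting and the treatment of reads that map to several places are not given in the sources used here; they decide how reads of overlapping genes, antisense genes and near-identical gene copies are split.

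Columns were matched to samples through the library codes in the labels, and groups follow the genotype label. Gene names, positions and 3' UTRs came from GENCODE M21 on GRCm38; 49056 of the 49315 gene IDs matched and 259 did not. Total counts ran from 43110251 to 51688514 per library, and 0 columns were not mapped to a sample. Within groups, chi-square per degree of freedom between library pairs ran from 23.5 to 114, so no pair agreed within sampling noise and all 7 libraries were counted as samples.

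Analyses used R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Counts were filtered with filterByExpr (minimum count 10), normalized with TMM and fitted with robust glmQLFit; glmQLFTest compared KO with flox, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The biological coefficient of variation was 16.9%. Standard errors are those implied by the quasi-likelihood F statistic, and 95% intervals use its degrees of freedom. CPM values use TMM-scaled library sizes, and log2 CPM a prior count of 2. All fold changes are log2, KO minus flox.

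Named genes followed a rule set before the data were examined: up to 10 rises and 10 falls by size among genes past the threshold with a mean log2 CPM of at least 1 and no overlap between groups, filled up to 5 by lowest p where few pass; up to 4 members with the lowest p of each fixed list; and Cxcr4, Cxcl12 and the genes of the deleted locus. Predicted models, pseudogenes, immunoglobulin and T cell receptor segments, Y-linked genes and Xist were left out of the first part. Other genes are named after their values were seen. In the fixed lists these are Fosb, Jun, Adipoq, Cd74, Ciita, Clec9a and Zbtb46, and in the lists of other tissues all members.

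The 36 gene lists, also fixed then, covered haematopoietic stem and progenitor, monocyte and macrophage, neutrophil primary granule, neutrophil secondary granule, mature neutrophil, eosinophil, basophil and mast cell, erythroid, megakaryocyte and platelet, B lineage, plasma cell, T cell, NK cell, dendritic cell, marrow stroma and bone, endothelial, adipocyte and skeletal muscle genes, the CXCR4 axis and marrow egress, angiogenic factors, reported miR-181 targets, interferon response, inflammatory cytokines, both cell cycle phases, immediate early and stress genes, hypoxia, glycolysis, cholesterol synthesis, the unfolded protein response, sex chromosomes, the miR-181 loci and neighbours, and ribosomal protein, mitochondrially encoded, oxidative phosphorylation, histone and immunoglobulin variable segment genes. The list of miR-181 loci had fewer than 5 tested members and was not tested as a list. Lists were tested with camera (preset correlation 0.01) on log2 CPM, with an estimated correlation as an alternative, and with fry; members passing were counted over all genes and adjusted over the list alone. Further lists of intestinal, neuronal, liver, kidney, lung, pancreas, cartilage, gut smooth muscle and core clock genes were written after the calls were seen.

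Seed sites of the miR-181 family (7mer-m8 and 8mer) were searched in the longest annotated 3' UTR of each gene. Genes with only other site types count as genes without a site. With camera, all site genes were set against genes without a site, and 8mer genes against all other tested genes with a 3' UTR. Both sets were also set against 10000 random lists matched on expression and 3' UTR length. Single genes of interest were also compared with an exact two-sided permutation test over all 35 splits of the libraries.

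On counts simulated for the 17920 tested genes, the edgeR test recovered 44% of genes changed 1.5-fold, 56% changed 2-fold, 88% changed 3-fold and 92% changed 4-fold, with 11 false calls among 151. In 20 simulated runs of the list test, all 20 shifted lists and 0 unshifted lists were called, with genes drawn independently. Alternatives were other normalizations, DESeq2, limma-voom, other filters on low counts, non-robust dispersion, removal of haemoglobin and mitochondrial genes, other thresholds, the replicate number as a block, and leaving out each library. Removal of intestinal and neuronal genes, list tests on library size alone, and list tests without flox 1 with an estimated correlation were added after the data were seen.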

Results

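Gene expression was measured by poly(A)-selected RNA sequencing in bone marrow of mice on a chow diet after hindlimb ischemia, a surgical model of limb artery disease. The 3 control libraries (flox) came from mice with floxed alleles of the microRNA cluster miR-181a2b2, and the 4 knockout libraries (KO) from mice without it. The series title places the work in a study of the miR-181a/b and CXCR4 axis in diabetic limb ischemia, and the libraries analysed here are the chow arm. Total counts ran from 46151300 to 51688514 in flox and from 43110251 to 48320848 in KO. Of the 49315 genes in the table, 30951 had a count in at least 1 library and 17920 were tested. Nothing in the labels says that the libraries came from separate animals, so p-values measure only the spread between these samples, which may be technical. The first principal component held 34.7% of the variance and set flox 1 apart at a score of -58.7, against -14.2 and -5.48 for flox 2 and flox 3 and 16.6 to 23.2 for the KO libraries.

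The first question was whether the deleted locus could be read in these libraries. Mir181a-2 (chromosome 2, 38852735 to 38852810, GRCm38) and Mir181b-2 (chromosome 2, 38853830 to 38853918) had 0 counts in all 7 libraries, as did Mir181a-1 and Mir181b-1 on chromosome 1. Poly(A) libraries do not capture mature microRNAs, so these counts do not check the genotype labels. Gm44144, a predicted gene on the opposite strand whose span (chromosome 2, 38852978 to 38854937) contains Mir181b-2, had 0, 4 and 6 counts in flox and 5, 8, 4 and 2 in KO; its span also lies within Nr6a1 on the same strand, and the labels do not give the ends of the deletion. Nr6a1, the nuclear receptor gene whose span on the opposite strand covers the cluster, had 94, 84 and 87 counts in flox and 38, 89, 57 and 82 in KO (log2 fold change -0.33, SE 0.29, edgeR adjusted p = 0.671). Its antisense gene Nr6a1os had 11 to 13 counts in flox and 15 to 23 in KO (0.63, SE 0.31, adjusted p = 0.396). Because the strand setting of the counting is not given in the sources used here, reads of Nr6a1 and Nr6a1os cannot be told apart.

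Cxcr4, the chemokine receptor that retains blood cells in the marrow, differed by less than the spread between libraries. Its level was 356 ± 39.4 CPM (SD, n = 3) in flox and 388 ± 34.6 CPM (SD, n = 4) in KO. The log2 fold change was 0.13 (SE 0.10, 95% interval -0.10 to 0.35, edgeR adjusted p = 0.631), and an exact two-sided permutation test over the 35 splits gave p = 0.286, where the smallest possible p is 0.0286. Its ligand gene Cxcl12, made by marrow stroma, stood at 442 ± 209 CPM in flox and 257 ± 53.2 CPM in KO (log2 fold change -0.78, SE 0.32, edgeR adjusted p = 0.346; exact permutation p = 0.143), and without flox 1 the Cxcl12 log2 fold change was -0.33. The list of CXCR4 axis and marrow egress genes did not pass the list test (24 members tested, 18 lower, median -0.16, camera adjusted p = 0.0618), and 0 of its members passed, adjusted over the list alone or over all genes. Among its members with the lowest p, the neutrophil elastase gene Elane gave -0.59, the adhesion receptor gene Cd44 gave -0.22, the monocyte chemokine receptor gene Ccr2 -0.48 and the protease gene Mmp9 -0.30.

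The comparison over all genes asked which transcripts differ between KO and flox marrow. Genes typical of intestinal epithelium rose in KO. Clca1, a secreted goblet cell protein, went from 3.24 ± 0.0886 CPM (SD, n = 3) to 10.2 ± 1.05 CPM (SD, n = 4), a log2 fold change of 1.65 (SE 0.13, edgeR adjusted p = 0.00212). Fcgbp, a mucus protein, rose by 1.48 (SE 0.09, adjusted p = 0.00044) and Muc2, the main gel-forming mucin of the gut, by 1.24 (SE 0.14, adjusted p = 0.0175). Sis, the brush border sucrase-isomaltase, rose by 1.28 (SE 0.16, adjusted p = 0.0175). Snap25, a synaptic vesicle fusion protein of neurons, fell by 1.15 (SE 0.15, adjusted p = 0.0318), from 5.62 ± 0.645 to 2.53 ± 0.274 CPM.

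In all, 26 genes passed an edgeR quasi-likelihood test at an adjusted p of 0.05, 24 of them higher and 2 lower in KO. Among genes with a mean log2 CPM of at least 1, the other rises of the largest 10 were Cubn (1.38), Tff3 (1.32), Cyp4f14 (1.29), Mep1b (1.27), Tmigd1 (1.25) and Mep1a (1.24), with adjusted p between 0.0175 and 0.0405. Beyond these, Krt8, Apob, Pigr, Naaladl1, Krt19, Malrd1 (1.83, below that expression minimum), Vil1, Cdh17, Aoc1, Cdhr2, Myo1a, Clec2h, Muc3 and Fabp6 passed, named after their values were seen. The other lower gene was Col2a1, the cartilage collagen, at -1.45 (SE 0.21, adjusted p = 0.0405), which lay below the expression minimum for named genes. Snap25 and Col2a1 lost their calls whichever of the 7 libraries was left out (edgeR adjusted p from 0.0538 without KO 4 to 0.143 without KO 2 for Snap25). The next lower genes by p missed the threshold: S100a6 (-0.59, adjusted p = 0.0946), Col6a2 (-0.93, 0.0965), Igfbp4 (-0.59, 0.0965) and Dynlt1b (-0.53, 0.0984).

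**Figure D1:**
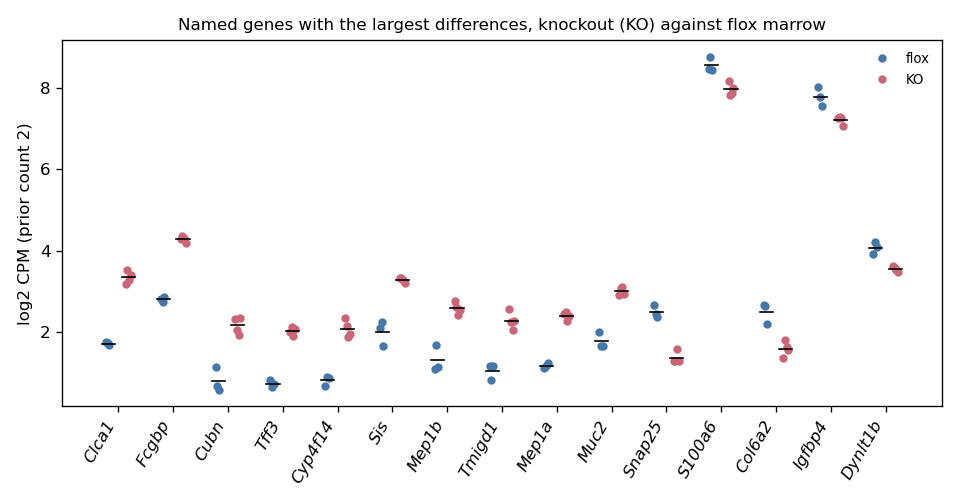
Log2 CPM (prior count 2) of the 10 largest rises among genes with a mean log2 CPM of at least 1 and of 5 lower genes in the 3 flox libraries (blue) and the 4 KO libraries (red); each point is a library and each bar a group mean. Libraries of the 2 groups do not overlap for any gene shown; of the lower genes only Snap25 passed the threshold, S100a6, Col6a2, Igfbp4 and Dynlt1b having missed it.

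Most listed genes of intestinal epithelium, neurons and cartilage moved in 1 direction per list, though only 1 neuronal and 1 cartilage gene passed. Over a list of 70 intestinal epithelial genes, written after the calls were seen and holding all 24 genes that rose, 69 were higher in KO, with a median log2 fold change of 1.08. Summed, these genes stood at 347 ± 23.5 CPM (SD, n = 3) in flox and 603 ± 59.0 CPM (SD, n = 4) in KO. Of 39 tested neuronal genes, also listed after the calls were seen, 33 were lower, with a median of -0.65. Summed, the neuronal genes at 10 CPM or less (34) stood at 72.1 ± 2.35 CPM in flox and 55.6 ± 3.27 CPM in KO, while the sum over the whole list was higher in KO, at 862 ± 108 and 942 ± 93.7 CPM. Of 14 cartilage genes, listed after the calls were seen and holding the called Col2a1, 7 were tested, with a median of -0.55 and 6 lower. The count of 26 was 14 without flox 1, 4 without flox 2 and 3 without flox 3. It was 2 without KO 1, KO 2 or KO 3 and 4 without KO 4, and DESeq2 called 365 genes. With the intestinal and neuronal genes removed 0 passed, which the removal nearly fixed, as these lists hold 24 and 1 of the 26 genes. The unadjusted edgeR p was then under 0.05 for 2428 genes. At that unadjusted level the main test had 2520 genes (1056 higher, 1464 lower), where chance gives 896.

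Gene lists fixed before the data were examined separated lymphoid and early response genes, higher in KO, from megakaryocyte, stromal and granulocyte genes, lower in KO, by a camera test with a preset correlation. With an estimated correlation 0 of the 35 tested lists passed, the lowest adjusted p being 0.433, and 1 list had an unadjusted p under 0.05. The B lineage list was higher in all 21 of its members, with a median log2 fold change of 1.04. Il7r, the interleukin 7 receptor of B cell precursors, stood at 26.1 ± 12.5 CPM in flox and 59.4 ± 11.8 CPM in KO, and Rag2, a recombinase of antigen receptor genes, at 2.71 ± 2.08 and 7.08 ± 1.54 CPM. All 18 megakaryocyte and platelet genes were lower, with a median of -0.65, among them the platelet adhesion genes Selp (-0.78), Gp1bb (-0.75) and Itgb3 (-0.59). With the preset correlation, 22 of the 35 tested lists passed, 10 higher and 12 lower. The rotation test fry called 0 lists (lowest adjusted p = 0.175), and 0 members of any list passed over all genes in the planned edgeR test, while DESeq2 called some, among them Egr1 (adjusted p = 1.36e-06).

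**Figure D2:**
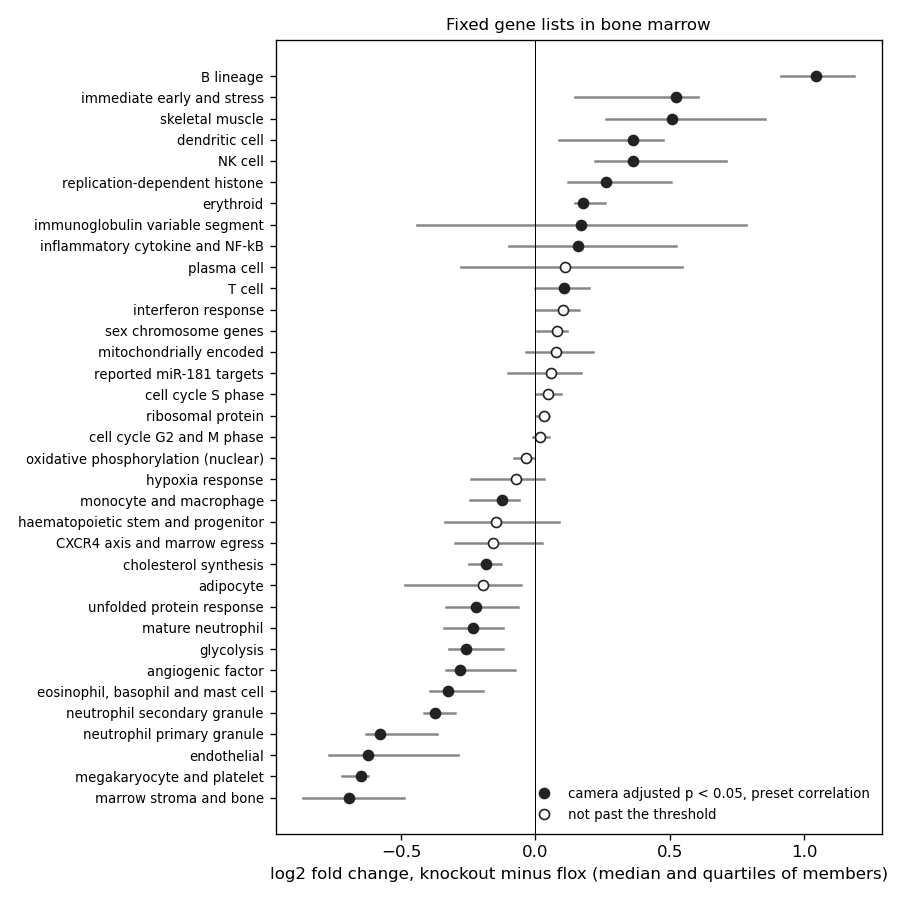
Median log2 fold change, KO minus flox, of the members of each of the 35 tested lists (points) with the lower and upper quartile (lines). Filled points passed the camera test with the preset correlation; the B lineage list lies highest at 1.04 and the marrow stroma and bone list lowest at -0.70.

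Among the lists higher in KO, B lineage had camera adjusted p = 5.55e-08, and 0 of its 21 members passed adjusted over the list alone; adjusted p = 0.433 with an estimated correlation. Flox 1 had the lowest B lineage score of the 7 libraries, at a mean log2 CPM of 3.14 against 5.48 and 6.08 in flox 2 and flox 3 and 6.19 to 6.55 in KO, and without flox 1 the list median was 0.53 and without flox 3 it was 1.66. Immediate early and stress genes were higher in 19 of 23 members (median 0.52, adjusted p = 2.62e-07), and 12 rose adjusted over the list alone; adjusted p = 0.433 with an estimated correlation. The transcription factor genes Egr1 (1.52, SE 0.31), Jund (0.52) and Junb (0.50) and the growth inhibitor gene Btg2 (0.55) led this list, and Fosb, chosen after its value was seen, gave 3.01 (SE 0.81). Natural killer genes (median 0.36, 14 of 15 higher, adjusted p = 0.000147, and 0.433 with an estimated correlation) included the receptor genes Klrb1c (0.60) and Il2rb (0.23). The 1 lower member was Nkg7 (-0.58), which is also in the neutrophil primary granule list. The natural killer median was 0.20 without KO 1. Dendritic cell genes (0.36, 16 of 18 higher, adjusted p = 0.000233) included Siglech, a plasmacytoid cell receptor (0.47), and H2-Aa, an antigen presentation gene (0.44), both past the threshold adjusted over the list alone; adjusted p = 0.433 with an estimated correlation. The antigen presentation genes Cd74 (0.48) and Ciita (0.61), which B cells share, and the dendritic cell genes Clec9a (-0.24) and Zbtb46 (0.04), all 4 chosen after their values were seen, did not pass adjusted over the list alone. Replication-dependent histone genes were higher in 49 of 56 members (0.26, adjusted p = 1.17e-06), with Hist1h2bg at 1.33; adjusted p = 0.433 with an estimated correlation. Near-identical copies can share reads in this family and among the haemoglobin genes, so single members there are uncertain. The libraries were poly(A)-selected, and how far that selection captures histone messages was not tested. S phase genes, a separate list, did not pass (median 0.05, camera adjusted p = 0.164).

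The test also called 5 more lists higher in KO, at higher adjusted p. All 27 erythroid genes were higher (median 0.18, adjusted p = 0.000498), with the globin genes Hba-a2 at 0.50 and Hbb-bt at 0.42; adjusted p = 0.544 with an estimated correlation. Without flox 2 that median was -0.000295 and the call was lost, and it was 0.39 without flox 1 and 0.09 without KO 3. Skeletal muscle genes (11 of 11 higher, 0.51, adjusted p = 0.00207, and 0.433 with an estimated correlation) included the calcium pump gene Atp2a1 (0.75). In this list 1 member passed adjusted over the list alone, the filament gene Des (1.11), which is also in the later list of gut smooth muscle genes. The skeletal muscle call was lost without KO 3, at a median of 0.10. T cell genes (0.11, adjusted p = 0.0195; adjusted p = 0.458 with an estimated correlation) included the kinase gene Lck (0.34) and the adhesion gene Cd2 (0.54). Immunoglobulin variable segments (198 tested, 112 higher, 0.17, adjusted p = 0.0316; adjusted p = 0.433 with an estimated correlation) and inflammatory cytokine genes (24 tested, 15 higher, 0.16, adjusted p = 0.0377; adjusted p = 0.517 with an estimated correlation) followed, the latter with the chemokine genes Ccl4 (1.16) and Cxcl2 (0.69). The T cell call was lost without flox 3 (median -0.03), KO 1 (0.10) or KO 3 (0.08), with 0.21 without flox 1 and 0.17 without KO 4. The variable segment call was lost without flox 2 (0.20), flox 3 (0.21) or KO 1 (0.08), with 0.38 without flox 1 and 0.02 without KO 4, and the cytokine call without flox 1 (0.15), flox 3 (0.14), KO 1 (0.06) or KO 2 (0.20).

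Megakaryocyte and platelet genes had camera adjusted p = 1.81e-07, and 11 of 18 fell adjusted over the list alone; adjusted p = 0.433 with an estimated correlation. Marrow stroma and bone genes were lower in 20 of 21 members (median -0.70, adjusted p = 6.86e-06), and 5 fell adjusted over the list alone; adjusted p = 0.433 with an estimated correlation. They included the matrix genes Sparc (-0.84, SE 0.19) and Col1a2 (-0.79, SE 0.21), the osteoblast regulator Sp7 (-1.22) and the osteoclast protease Ctsk (-1.14). Without KO 4, Col1a2 passed over all genes (-1.03, edgeR adjusted p = 0.00974). Primary granule genes of neutrophils were lower in 12 of 12 members (-0.58, adjusted p = 7.02e-06), and 10 fell adjusted over the list alone; adjusted p = 0.433 with an estimated correlation. Mpo, the granule peroxidase, stood at 2666 ± 754 CPM in flox and 1787 ± 263 CPM in KO, and Prss57 gave -0.65. Secondary granule genes (-0.37, adjusted p = 1.89e-05) had 8 members that fell adjusted over the list alone, led by Fcnb (-0.44) and Ceacam10 (-0.50); adjusted p = 0.433 with an estimated correlation. Without flox 1 the medians were -0.36 for megakaryocyte and -0.44 for stromal genes, and without flox 2 they were -0.26 for primary and -0.20 for secondary granule genes.

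Among the other lists lower in KO, endothelial genes had a median of -0.62 (14 of 16 lower, adjusted p = 0.00213), with the receptor genes Tie1 at -0.57 and Kdr at -0.98 and the sialomucin gene Emcn at -0.87; adjusted p = 0.468 with an estimated correlation. Without flox 1 this median was -0.23 and the call was lost. Angiogenic factor genes (22 of 24 lower, -0.28, adjusted p = 0.000832) included the semaphorin and growth factor receptor gene Nrp2 (-0.52) and Anxa2 (-0.33), with 0 members past the threshold adjusted over the list alone; adjusted p = 0.433 with an estimated correlation. Glycolysis genes (19 of 21 lower, -0.26, adjusted p = 2.55e-05) had 7 members that fell adjusted over the list alone, among them the hexokinase Hk3 (-0.37) and the aldolase Aldoa (-0.31); adjusted p = 0.433 with an estimated correlation. Mature neutrophil genes (-0.23, adjusted p = 0.000186; adjusted p = 0.433 with an estimated correlation) had BC100530 at -0.93. Cholesterol synthesis genes had a median of -0.18, with 23 of 24 lower (adjusted p = 0.000337; adjusted p = 0.458 with an estimated correlation). Unfolded protein response genes (-0.22, adjusted p = 0.00437; adjusted p = 0.433 with an estimated correlation) had Asns, asparagine synthetase, at -0.36. Eosinophil, basophil and mast cell genes (-0.33, adjusted p = 0.00606; adjusted p = 0.538 with an estimated correlation) had Siglecf at -0.36. Monocyte and macrophage genes (-0.12, adjusted p = 0.028; adjusted p = 0.468 with an estimated correlation) had the integrin gene Itgam at -0.37 and the oxidase gene Cybb at -0.29. Without flox 1 the angiogenic median was -0.16; without flox 2 the glycolysis median was -0.14, and the cholesterol (-0.06) and unfolded protein (-0.08) calls were lost. The eosinophil call was lost without KO 3 (-0.13), and the monocyte call without flox 1 (-0.05), KO 3 (-0.08) or KO 4 (-0.09), with -0.19 without flox 2 or KO 1.

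**Figure D3:**
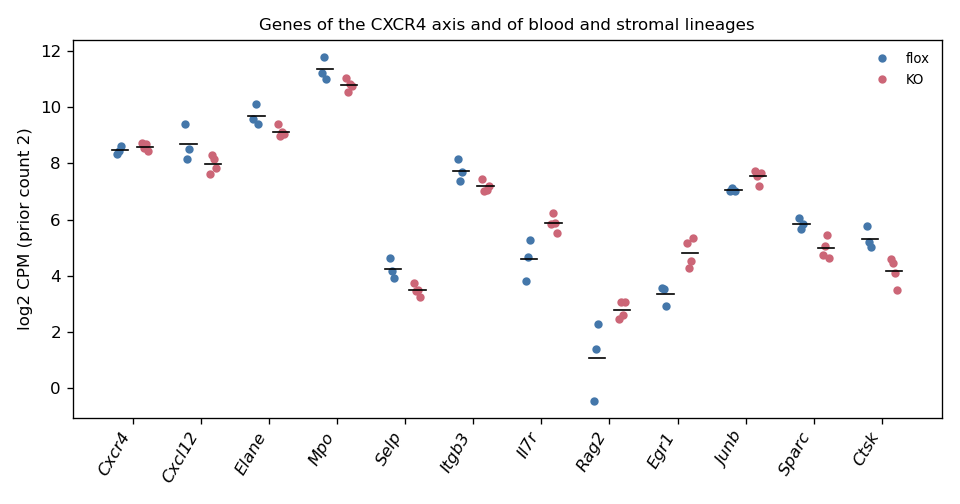
Log2 CPM (prior count 2) of 12 genes of the CXCR4 axis and of blood and stromal lineages in the 3 flox libraries (blue) and the 4 KO libraries (red); points are libraries and bars group means. Rag2 and Il7r are lowest in flox 1, and Cxcr4 overlaps between the groups.

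The other lists did not pass. Median log2 fold changes were -0.15 for haematopoietic stem and progenitor genes (adjusted p = 0.193), with Hoxa9 at -0.78 and Sox4 at 0.83, 0.11 for plasma cell genes (0.188), 0.10 for interferon response genes (0.251), -0.07 for hypoxia response genes (0.127), and 0.05 and 0.02 for S phase and G2 and M phase genes (0.164 and 0.71). Ribosomal protein genes gave 0.03 (0.0616), nuclear oxidative phosphorylation genes -0.04 (0.0521), mitochondrially encoded genes 0.08 (0.075) and sex chromosome genes 0.08 (0.193). The adipocyte list gave -0.20 (adjusted p = 0.167), with the adipokine gene Adipoq, chosen after its values were seen, at 11.2 CPM in flox and 6.85 CPM in KO and the lipid droplet gene Plin1 at 0.549 and 0.188 CPM. These levels are given because the extraction protocol in the labels speaks of fat tissue, while the source label is bone marrow. The most abundant gene was Hbb-bs or S100a9 in every library, and Mpo stood at 2666 CPM in flox and 1787 CPM in KO. These levels argue against fat as the main tissue sequenced.

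The last comparison asked whether messages with binding sites for miR-181 differ when 2 members of the family are deleted. Genes with a seed site of the types searched in the 3' UTR did not differ by the list test from genes without one. Mature microRNAs of the family were not measured, so this does not say that loss of the cluster leaves its targets unchanged. The median log2 fold change was -0.016 for 2542 genes with a site and -0.018 for 11733 genes without, and -0.0054 for the 830 genes with the longest site type, and 0 genes with a site passed the edgeR test. Random lists matched on expression and 3' UTR length gave medians from -0.022 to -0.0096 in 95% of draws for the first set. For the second they ran from -0.0285 to -0.0035, so both medians lay within their range. The second median lay near the upper end, at percentile 94.7, with 48.6% of its genes higher against 45.5% of genes without a site. Site genes could themselves be drawn into the random lists. Of reported miR-181 targets, 18 of 30 were higher and 12 lower (median 0.06, camera adjusted p = 0.193), with the activation marker Cd69 at 0.70, Fos at 1.21 and the protease inhibitor Timp3 at 19.8 CPM in flox and 9.90 CPM in KO, 0 of 30 past the threshold adjusted over the list alone. On simulated log2 CPM values for these 14275 genes, a shift of 0.1 was called in 50 of 50 runs. The values were drawn from normal distributions with genes independent, not as counts.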

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

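The tests in this part were all chosen after the results were seen, except the count over splits. Among 156 values examined in the 4 KO libraries, 10 had a single library far from the others, where chance gives about 7.8. KO 3 was the library apart in 5 of them, KO 1 and KO 4 in 2 each and KO 2 in 1. In KO 3, haemoglobin genes took 5.91% of counts (4.75% to 4.84% in the other KO libraries), the most abundant gene 3.10%, Hbb-bt had a log2 CPM of 12.7, Siglecf 3.25 and the endothelial list a score of 2.35. In KO 1, the interferon response list had a score of 5.46 (4.73 to 4.76 in the others) and Igfbp4 a log2 CPM of 7.05. In KO 4, Snap25 had a log2 CPM of 1.57 and Col1a2 6.11. In KO 2 the sex chromosome list had a score of 6.06.

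Intestinal epithelial genes were higher in KO. Of the 35 splits of the 7 libraries only the real one, 1 split, gave as many as 26 genes, the highest other giving 1. With 35 splits an exact permutation p cannot fall below 0.0286, so a chance split is unlikely but not excluded. Gut tissue carried over with single samples would vary between libraries, but the summed CPM of the 56 members at 10 CPM or less varied by at most 9.38% (CV) within a group. That of all 70 members varied by at most 9.78%. A small spread helps a gene to be called, so the 46 uncalled members were also summed, and varied by at most 11.8%. The 36 of these at 10 CPM or less varied by at most 12.4%. Sums can hide single members: in KO, Fabp2 stood at 27.7 ± 13.5 CPM (SD, n = 4), Apoa4 at 5.31 ± 2.44 CPM and Rbp2 at 1.30 ± 0.782 CPM. Other members varied little, as Krt19 at 5.53 ± 0.132 CPM in KO. Carry-over that reaches only some of these genes is therefore not excluded. A mixing of all other tissues into the KO libraries would raise neuronal genes too, and their median was -0.65. This says nothing of a mixing without nervous tissue. Medians were above 0 for skeletal muscle (0.51), liver (1.53, over 3 tested genes) and gut smooth muscle (0.11). They were below 0 for cartilage (-0.55), adipocyte (-0.20), lung (-0.17) and kidney (-0.04) genes, so these lists do not decide it. Intestinal reads or RNA at a level set per group stay open: 98.6% of members were higher in KO, 97.8% of the 46 uncalled members, the labels give no batch, pool or lane, and a batch that follows the groups and the genotype cannot be told apart. The genotype may also be the source, which was not tested.

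Most neuronal genes were lower in KO, with 26 of 39 lower and 1 higher without overlap between the groups, where chance gives 5.71% for both directions together and 13.6% of all tested genes did not overlap. Brain tissue carried over with single samples would vary between libraries, but the summed CPM of the 34 members at 10 CPM or less varied by at most 5.89% within a group. Some single members varied more, as Nefh at 5.19 ± 3.44 CPM in flox, while Celf4 stood at 2.60 ± 0.0675 CPM there. The sum of all members, which includes 5 above 10 CPM, varied by at most 12.5% and was higher in KO (862 CPM in flox, 942 CPM in KO), and the limit to members at 10 CPM or less was set after these sums were seen, here and for the intestinal genes. What sets the level per group remains open, as for the intestinal genes.

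Blood lineage lists shifted in both directions. By the limit set for it after the results were seen, flox 1 alone narrowly did not account for the B lineage shift. Without that library the list passed the preset test at a median of 0.53, against 1.04 with it, the limit being 0.5 of the value with it. That test presets a correlation of 0.01, while the estimate for this list over all 7 libraries was 0.80, so passing it does not decide the question. With an estimated correlation 0 lists passed with or without flox 1. Dilution by one cell type stays open: more B lineage cells would also lower the share of the other cells, and megakaryocyte genes had a median of -0.65, but erythroid (0.18), NK (0.36) and dendritic (0.36) medians were above 0, none past the threshold with an estimated correlation. A difference in the cell makeup of the marrow samples, from the genotype or from the dissection, may remain and was not tested.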

How the results depend on the processing

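The alternatives chosen after the data were seen were the removal of intestinal and neuronal list genes, list tests on library size only, and list tests without flox 1 with an estimated correlation. Of the 26 genes, all 26 kept their call with DESeq2 size factors, library size only, the stricter filter and haemoglobin and mitochondrial genes removed, which called 29, 38, 31 and 29 genes; upper-quartile normalization called 23, all among the 26. Counts that moved by over 1.5 times were 365 with DESeq2 (233 higher, 132 lower), 13 with limma-voom (12 and 1) and 112 with no filter (84 and 28). There were 16 with non-robust dispersion (15 and 1), 12 against a 1.2-fold change (12 and 0) and 66 at an adjusted p of 0.1 (58 and 8). The causes of these moves were not tested. With intestinal and neuronal genes removed, 0 passed (0 and 0, lowest edgeR adjusted p = 0.214). Those lists were written after the calls and hold 24 and 1 of the 26 genes, so nearly all of that fall was fixed by the removal. Leaving out 1 library gave 2 to 14 genes, 2 to 14 higher and 0 to 1 lower, from fewer samples. Fcgbp and Clca1 passed in all 7 of these fits.

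The replicate numbers showed no clear pairing: same-numbered libraries correlated at -0.022, 0.077 and 0.023, and the other pairs at -0.085 to 0.054. With so few shared numbers a pairing cannot be excluded. With the replicate number as a block, 4 genes passed (3 higher, 1 lower), 1 of them shared with the main 26. The others were Jun (1.51, edgeR adjusted p = 0.00891), named after its value was seen, Egr1 (1.59, 0.0205) and Col1a2 (-1.03, 0.028). KO 4 has no flox library of the same number, so it adds nothing to the genotype estimate in the block fit. The Col1a2 call is therefore not separate from its call without KO 4, also at -1.03. In the block fit the seed-site median was -0.016.

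Cxcr4 stayed short of the threshold in every alternative, from 0.05 without flox 1 to 0.21 without flox 3. Lists passing numbered 19 to 25 in the other alternatives and 0 with an estimated correlation, with flox 1 left out or not (lowest camera adjusted p = 0.387 and 0.433). Of the 22 called lists, 20 kept their call with DESeq2 size factors or library size only. With the stricter filter or the block 21 did, and 18 to 21 without 1 library. Seed-site genes changed direction against genes without a site in the block fit and in 4 of the 7 fits without 1 library, with medians from -0.0284 to 0.000132 over all 7; all stayed short of the threshold, and the cause was not tested. Zbtb46 ran from -0.14 without flox 2 to 0.24 without flox 1, not past the threshold in either. List medians near 0 also changed sign in some fits without 1 library, the called T cell and erythroid lists among them, and 0 called lists passed in the opposite direction. Genes changed 1.5-fold were recovered in 44% of simulated cases, which limits what a missed call says.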

Other observations

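The tests here were chosen after the results were seen, except the control sites of the seed test. Of the gut smooth muscle genes, Myh11 (0.90), Pgm5 (1.42), Des (1.11), Cnn1 (0.85) and Actg2 (0.61) were higher in every KO library than in every flox library, while Acta2 gave -0.10; the list of 12 had a median of 0.11, 7 higher and 5 lower, and 0 passed. Among neuronal genes, Rbfox1 stood at 1.62 CPM in flox and 0.812 CPM in KO, and log2 fold changes were for Celf4 -0.74, Slc17a7 -1.60 and Myt1l -1.04. In cartilage genes, Col11a2 gave -0.55 and Comp -1.34. Liver, kidney and lung lists had 3, 3 and 2 tested members with medians of 1.53, -0.04 and -0.17, and no pancreas gene was tested. The 3 tested liver genes summed to 0.655 CPM in flox and 1.69 CPM in KO. Lct was the intestinal gene that was lower.

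Ddx3y, Kdm5d and Uty had 3643 to 4205, 1078 to 1377 and 654 to 984 counts and Xist at most 20, in all 7 libraries. The Y-linked gene Eif2s3y varied more, with 185, 1000 and 1611 counts in flox and 2657, 1620, 3353 and 3088 in KO (log2 fold change 1.57, edgeR adjusted p = 0.396).

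A hypothesis was that the groups were collected at different times of day. The core clock list had 15 tested members, 9 higher and 0 past the threshold. Genes of the 2 limbs of the clock would then move apart, but Arntl (0.81) of one limb and Tef (0.38) and Nr1d2 (0.21) of the other were all higher in KO without overlap, and Per3 gave -0.30. The limb medians differed by -0.16, and with 1 such gene in the first limb a different time of collection may remain possible.

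The composition of the 3' UTR was to be weighed for a seed-site shift. Of 209 control sites of the same base composition, 86.6% gave a statistic as large as the miR-181 site, so there was no shift to account for and this stays undecided.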
